A study of Homo sapiens with 18 samples.

How the data were processed

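RNA from 18 samples of KM12SM and SW620 cells, both human colorectal cancer lines, was measured on Clariom S oligonucleotide arrays, 1 array per sample. Per the labels' protocols, total RNA was biotin-labelled, and silencing used an shRNA against CDH17. Group and replicate number were read from each sample's title. They gave 3 unmodified KM12SM arrays, 3 KM12SM sh60 arrays, 6 unmodified SW620 arrays, 4 SW620 sh60 arrays and 2 SW620 arrays titled SCR, an abbreviation the labels do not spell out. Per the labels, the treatment text on silencing stands on every sample, the arrays taken here as unmodified included, so the groups rest on the titles. The labels do not say that replicates of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

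The authors deposited log2 expression values with 2 decimals, 1 value per probe set and array, made with Transcriptome Analysis Console per the submitters' processing notes. Its version, the background correction, the normalization and any filter are not given in the sources used here. Array medians lay between 6.28 and 6.43, and the SD of an array's values between 1.93 and 2.22. The number of arrays per group limits the precision, and signal near the bottom of the scale is compressed towards the background, so fold changes of weakly expressed genes are likely to be understated. The values were used as deposited, without further scaling. As a measure of background, chosen after the data were seen, the 95th percentile of the 348 probes of olfactory receptor genes was taken on each array (4.99 to 5.60). Where a group did not lie above it on every array, the fold is given as at least the one found when each of its signals is replaced by the higher of signal and background. No fold is given where that bound is under 1. Among genes named by the rule below, some had a lower group not above background on every array. These were 24 of the 91 for silencing in KM12SM, 25 of the 67 for SW620 and all 11 between the unmodified lines. Their log2 fold changes are then differences of measured signal and do not measure expression. Of the 21448 probe sets, called probes here, 17709 carry 1 gene name in the platform's annotation, 0 carry several, and 3739 are unnamed here, which does not mean that they have no gene. All 17709 names were found in a RefSeq gene annotation of the human assembly GRCh38.p14, and 0 symbols changed. The genome build behind the array's annotation is not named, so chromosome names are given and coordinates are not. Of the gene names, 20 have more than 1 probe.

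Comparisons were fitted with limma 3.58.1 in R 4.3.3, with the package data.table (1.17.8). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A linear model of 5 group means was fitted to all 18 arrays, which leaves 13 residual degrees of freedom (7.24 prior degrees of freedom after empirical Bayes moderation). The adjusted p-values come from limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all 21448 probes, and 0.05 was the threshold. The contrasts were sh60 minus unmodified in each line, sh60 minus SCR and SCR minus unmodified in SW620, the difference between the silencing effects of the lines, and KM12SM minus SW620 without silencing. A gene or list is said to have risen, fallen or changed only where its adjusted p is under 0.05. CDH17 was also compared by a two-sided exact permutation test of the group means.

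The groups, contrasts, tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. The 26 lists held 482 members, of which 429 were measured. A member absent from the array was looked up under its synonyms, but a current symbol was never read as a synonym of another gene. They were tested with limma's camera, which compares a list with all other probes, at its preset inter-gene correlation of 0.01 and with adjustment over the 26 lists within a comparison. Beside it stand camera with the correlation estimated per list, and fry, whose directional p asks whether the members of a list move on balance one way. Probes of one list were also adjusted over the list alone. The lists covered cadherins and desmosome, integrins and focal adhesion, tight junction, intestinal epithelial identity, Wnt beta-catenin targets, mesenchymal genes, secreted proteases and invasion, mitosis, DNA replication, p53 targets, type I interferon response, antigen presentation, NF-kB inflammatory genes, ERK output, cholesterol synthesis, fatty acid synthesis, amino acid response, endoplasmic reticulum chaperones, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, oxidative stress and detoxification, metallothioneins, replication-dependent histones, and markers of fibroblasts and of blood cells, which these lines should lack.

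CDH17 is named in every comparison. For silencing in each line, the rule took the 10 genes that rose most and the 10 that fell most among called probes with 1 gene name whose arrays did not overlap between the groups. It added the 4 members with the lowest p from each list that was called or held at least 3 called members. For the other contrasts it took 5 genes in each direction, for the line difference without the condition on overlap, and for genes changed in both lines the 10 in each direction with the largest smaller change. Genes named outside this rule are marked as chosen after their values were seen.

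The test was checked on simulated arrays with the real probes' means and spreads, with 50 probes shifted per size. For silencing in KM12SM the procedure recovered 40% of shifts of 1 on the log2 scale and 98% of shifts of 2, with 7 false calls among 21448 probes. For silencing in SW620 it recovered 66% and 100%, with 9 false calls. Against SCR it recovered 28% and 96%, with 6 false calls. For SCR against unmodified SW620 it recovered 54% and 98%, with 2 false calls, and for the lines at baseline 66% and 100%, with 6. With the DNA replication list shifted by -0.50, camera called that list and 0 of the other 25 lists in the simulated KM12SM comparison. The simulated errors were independent between probes and between arrays, whereas the real DNA replication list had an estimated correlation of 0.47. These checks therefore do not show how many false calls arise from correlated genes or from sets of similar arrays.

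Alternatives chosen before the data were examined were each line fitted alone, quantile normalization, subtraction of array medians, removal of probes below the 30th percentile of mean signal, empirical Bayes moderation with trend and robust settings, array weights, the replicate number as a block, a minimum absolute log2 fold change of 1, 1 value per gene, sh60 against the mean of both SW620 controls, the same sign against both controls, and the loss of each array in turn. After the data were seen, further alternatives were added. The 12 SW620 arrays fall into 2 sets by the sign of their first principal component, and this set was used as a block and to make comparisons within a set. The sets come from the same values that are tested, so adjusted p-values with the block or within a set can be too small. SW620 sh60 arrays 1 and 3, the ones with the lowest correlation with the other arrays of their line, were left out, and so were the probes of chromosome X genes. XIST and genes of the Y chromosome were left out of all named results.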

Results

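Gene expression was profiled in KM12SM, a liver-metastatic human colorectal cancer line, and SW620, a line from a lymph node metastasis of colorectal cancer, with and without shRNA silencing of CDH17. CDH17 encodes liver-intestine cadherin, a cell adhesion protein of the intestinal epithelium. The series holds 18 Clariom S arrays with normalized log2 signals for 21448 probes. KM12SM was represented by 3 unmodified arrays and 3 arrays of cells carrying the shRNA sh60, and SW620 by 6 unmodified arrays, 4 sh60 arrays and 2 arrays of a control named SCR in the labels. The study's title gives its purpose as the expression profile that follows CDH17 silencing in these lines. Replicate arrays of a group correlated with r between 0.924 and 0.993, and arrays of the different lines with r between 0.862 and 0.930, across probes, which are not independent replicates.

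CDH17 itself was lower in the sh60 arrays of both lines. In KM12SM its signal fell from 9.74 ± 0.29 (SD, n = 3) to 5.68 ± 0.23 (SD, n = 3), a log2 fold change of -4.06 (SE 0.25), or 16.7-fold (limma adjusted p = 1.7e-09). In SW620 it fell from 4.96 ± 0.38 (SD, n = 6) to 3.94 ± 0.33 (SD, n = 4), a log2 fold change of -1.02 (SE 0.20, limma adjusted p = 0.0066). No fold is given there, since CDH17 was above the array background on 1 of 6 unmodified arrays and on 0 of 4 sh60 arrays. The SCR arrays held more CDH17 than unmodified SW620, at 6.93 ± 0.07 (SD, n = 2), a rise of 1.98 (SE 0.25, adjusted p = 0.00031), and sh60 lay at least 2.82-fold below SCR (log2 fold change -3.00, SE 0.27, adjusted p = 3.2e-06). Against unmodified SW620 the two-sided exact permutation test gave p = 0.0095 over 210 splits, whereas 3 arrays against 3 cannot give less than the p = 0.1 found by the exact test in KM12SM. In unmodified SW620 arrays CDH17 stood between the 20.7th and 36.6th percentile of all probes, near the weak end of the scale, and in unmodified KM12SM arrays between the 92.8th and 94.7th.

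**Figure D1:**
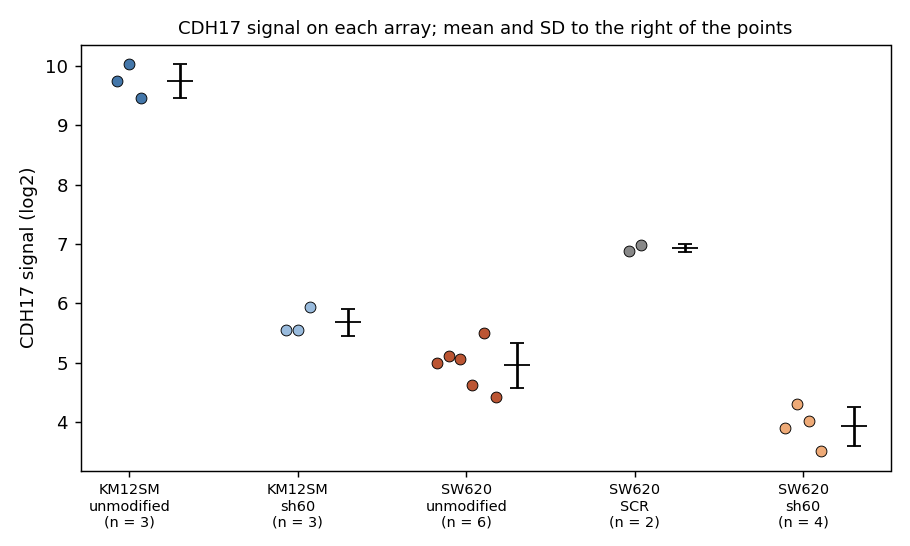
CDH17 signal (log2) on each of the 18 arrays, by cell line and treatment, with the mean and SD of each group beside its points. The 3 KM12SM sh60 arrays lie between 5.55 and 5.94 and the 3 unmodified ones between 9.46 and 10.0, whereas the 4 SW620 sh60 arrays (3.51 to 4.30) lie below all 6 unmodified SW620 arrays (4.42 to 5.50) and the 2 SCR arrays (6.88 and 6.98).

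The SW620 arrays also differed within treatment groups. Their first principal component, with 34.2% of the variance, put unmodified arrays 1 to 3, both SCR arrays and sh60 array 4 on one side (set 1), and unmodified arrays 4 to 6 with sh60 arrays 1 to 3 on the other (set 2). Between the unmodified arrays of these sets, 1917 probes differed (929 higher and 988 lower in arrays 4 to 6). As the sets were made from these same arrays, this describes their size and does not test them. Of the 10 lists called between them, metallothioneins (median log2 difference -2.69), oxidative phosphorylation (-0.88), ribosomal protein (-0.86) and oxidative stress genes (-0.40) were lower in arrays 4 to 6. Fatty acid synthesis (0.72), histones (0.63), DNA replication (0.55), cadherins and desmosome (0.53), cholesterol synthesis (0.47) and hypoxia genes (0.45) were higher there. With an estimated correlation only the metallothionein call held (adjusted p = 0.0061), while for the others adjusted p was between 0.128 and 0.759 with an estimated correlation. In sh60 arrays 1 to 3 the 282 expressed genes of chromosome X were lower than in unmodified arrays 4 to 6, with a median of -0.63 against -0.09 for autosomal genes. Of these X genes, 84.4% lay below the autosomal median. In sh60 array 4 against unmodified arrays 1 to 3 the X median relative to autosomes was 0.0033. Within set 2, with 3 arrays against 3, the CDH17 log2 fold change was -0.77 and did not pass (adjusted p = 0.09). Within set 1 CDH17 fell by 1.55 (adjusted p = 0.0011). That value rests on a single sh60 array, whose spread was taken from the other groups. With the set as a block it was -1.03 (adjusted p = 0.0036).

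**Figure D2:**
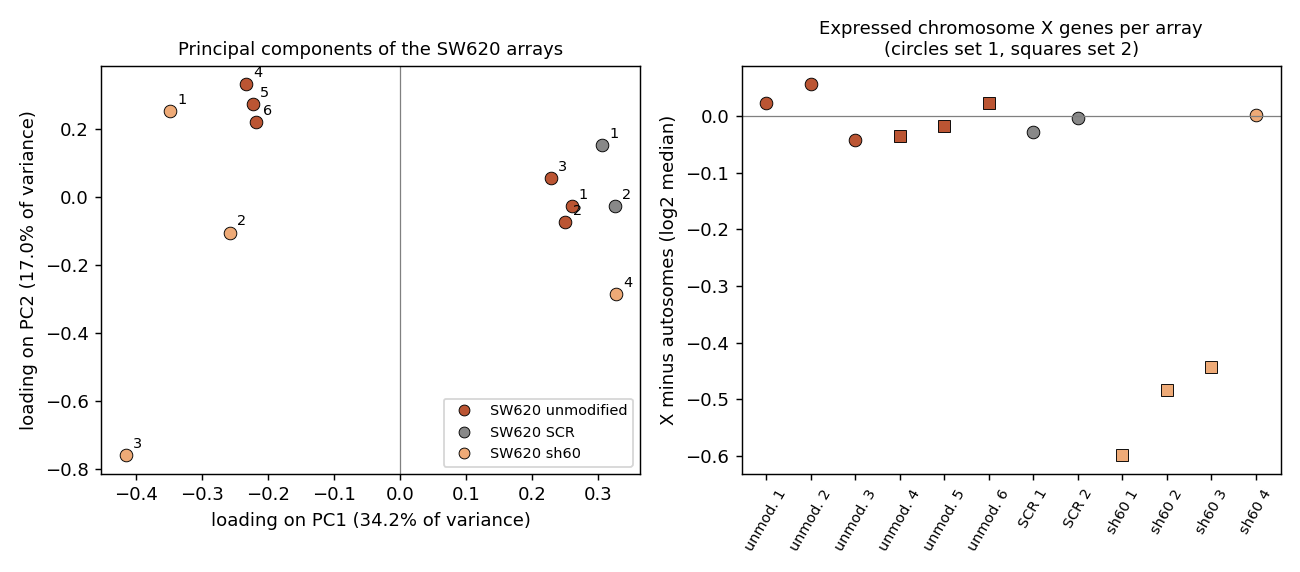
Left, loadings of the 12 SW620 arrays on the first and second principal components (34.2% and 17.0% of variance), numbered by replicate. Right, for each array the median log2 difference of expressed chromosome X genes from the unmodified SW620 mean, minus that of autosomal genes (log2), which lies near 0 on all arrays except sh60 arrays 1 to 3 (group median -0.54 against unmodified arrays 4 to 6).

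In KM12SM, silencing was accompanied by a small set of very large single-gene changes. SLC38A5, a glutamine transporter, fell at least 24.0-fold (log2 fold change -5.46, SE 0.24, adjusted p = 1.9e-11), from 9.92 ± 0.20 to 4.45 ± 0.20 (SD, n = 3 each), which is under the array background. CTSE, the aspartic protease cathepsin E, fell by 3.96 on the log2 scale, and CCNE2, the cyclin E2 that acts at the start of S phase, by 2.90. PUDP (-3.32), GASK1B (-3.14), the transcription elongation factor gene TCEA3 (-3.04), the hydrolase gene CMBL (-2.95), PIGW, which acts in glycosylphosphatidylinositol anchor synthesis (-2.87), and the potassium channel subunit gene KCNE3 (-2.84) fell too. CAPN6, a calpain family gene, rose at least 5.92-fold (log2 fold change 4.34, SE 0.27, adjusted p = 1.7e-09), from 3.29 ± 0.24 to 7.63 ± 0.18 (SD, n = 3 each). The zinc finger gene ZBTB10 rose by 4.05, the stress-response gene SESN3 (sestrin 3) by 3.57, CALB2 (calretinin, a calcium-binding protein) by 3.48, the transcription factor gene CREB5 by 3.12, the autophagy gene GABARAPL1 by 3.04, CREBRF by 3.01, the netrin receptor gene NEO1 (neogenin) by 2.95, MIA by 2.89 and ODAM by 2.77. Of 21448 probes, 2897 passed the threshold, 1265 higher and 1632 lower in sh60, and 554 and 940 of these changed at least 2-fold. With array medians subtracted the split was 968 higher and 1923 lower, so 33.5% instead of 43.7% of the called probes were higher. The count was 9263 with array weights and 5683 with the line fitted alone, and leaving out single arrays gave between 1823 and 3359.

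Of the 22 DNA replication genes, 14 fell in KM12SM and 8 did not pass the test, with 18 lower when adjusted over the list alone. The helicase subunits MCM3 (-2.36), MCM6 (-2.003) and MCM7 (-1.75) fell, and so did UHRF1 (-2.20), which maintains DNA methylation at replication. The list's median was -1.37 (camera adjusted p = 3.1e-13, and adjusted p = 0.527 with an estimated correlation). Of the 16 replication-dependent histone genes, which are transcribed in S phase, 6 fell and 10 did not pass (12 lower when adjusted over the list alone), among them H2AC4 (-2.35), H1-5 (-1.93), H2AC6 (-1.16) and H1-2 (-1.13). Their median was -1.02 (adjusted p = 4.8e-08, and adjusted p = 0.527 with an estimated correlation). The mitosis list had a median of -0.20 (adjusted p = 0.189), with 1 of 20 members lower. Among the 21 hypoxia and glycolysis genes 8 rose and 13 did not pass (9 higher when adjusted over the list alone), including ALDOC, an aldolase (2.38), the histone demethylase gene KDM3A (1.65), ADM, which encodes adrenomedullin (1.21), and the collagen prolyl hydroxylase gene P4HA1 (1.19). The list rose with a median of 0.46 (adjusted p = 0.00039, and adjusted p = 0.527 with an estimated correlation). Of the 17 protease and invasion genes 4 rose and 13 did not pass (4 when adjusted over the list alone), namely CTSD (1.28), PLAUR, the urokinase receptor (0.92), MMP1 (0.75) and MMP14 (0.65). Their median was 0.40 (adjusted p = 0.048, and adjusted p = 0.527 with an estimated correlation). The 8 metallothionein list members had a median of -1.45 (adjusted p = 0.043, and adjusted p = 0.656 with an estimated correlation), but 0 passed singly over all probes and 2 did when adjusted over the list alone. The single-gene tests use a spread shared by all 18 arrays, which includes the difference of -2.69 between the SW620 sets. Per array, the list's medians were 0.19, 0.09 and -0.27 in unmodified KM12SM and -1.40, -1.33 and -1.48 in sh60. With array medians subtracted the metallothionein call was lost (adjusted p = 0.0572). With dim probes left out both of these calls were lost (adjusted p = 0.0611 for proteases and 0.102 for metallothioneins).

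Other lists held called members in KM12SM without a call by camera. The fry test, which asks another question, called tight junction (adjusted p = 0.015), integrin and mesenchymal genes (adjusted p = 0.040 each). Of the lists that camera called in KM12SM, fry did not call histones (adjusted p = 0.0501) and metallothioneins (adjusted p = 0.275). In the list of intestinal identity genes, the homeobox gene CDX1 (-1.20), the lectin gene LGALS4 (-1.40) and the microvillus gene VIL1 (-1.47) fell, the mucosal peptide gene TFF3 rose (1.28) and 13 of 17 did not pass (list adjusted p = 0.370). Of the 13 tight junction genes, the claudins CLDN2 (-1.89) and CLDN7 (-1.19) fell, while TJP3 (1.05) and CGN (0.77) rose (list adjusted p = 0.189). Among the 18 Wnt targets, the stem cell receptor gene LGR5 (-2.62) and MYC (-1.41) fell and SOX9 (0.99) rose, with a list median of 0.25, a mean of -0.07 and adjusted p = 0.785, and ZNRF3 had a log2 fold change of -0.72 (adjusted p = 0.086). Among the 17 mesenchymal genes, FN1, which encodes fibronectin (1.07), CCN1 (0.98) and ZEB1 (0.93, under the background in both groups) rose, and SNAI1 had 0.84 (adjusted p = 0.060), with a list adjusted p = 0.256. ZYX (1.03) and PXN (1.24), focal adhesion proteins, rose, the integrin gene ITGA3 fell (-0.94), and ITGA6 had 0.71 (adjusted p = 0.0504), with a list adjusted p = 0.272. Interferon-response genes went both ways, with MX1 (-1.62), OAS1 (-1.33) and IFIT3 (-1.30) lower and IRF9 (1.12) higher (list adjusted p = 0.377). Of 16 antigen presentation genes 5 fell and 1 rose, among them the peptide transporter gene TAP2 (-1.68), the immunoproteasome gene PSMB8 (-1.13) and ERAP1 (-0.93) lower and HLA-C (0.89) higher (list adjusted p = 0.188).

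Among stress and signalling genes of KM12SM, the transcription factor genes DDIT3 (2.75), ATF3 (2.38) and CEBPB (0.95) of the amino acid response list rose and ALDH1L2 fell (-0.96), with a list adjusted p = 0.204. TNFAIP3, a feedback inhibitor of NF-kB signalling, rose by 2.61, NFKB2 by 1.15 and TNIP1 by 0.80, while the chemokine gene CXCL1 fell by 0.83 (list adjusted p = 0.312). Of 18 ERK output genes 5 rose and 2 fell, including FOSL1 (1.66), SPRED2 (1.16) and EPHA2 (0.92) higher and MYC lower (list adjusted p = 0.272). HMOX1, heme oxygenase 1, rose by 1.79, while ABCC2 (-1.37), AKR1B10 (-0.93, under the background in both groups) and ALDH3A1 (-0.91) of the same detoxification list fell (list adjusted p = 0.846). In lipid synthesis, ACSS2 (2.01) and FASN (1.25), the fatty acid synthase, rose while ACSL5 (-1.50) and ELOVL6 (-1.003) fell (list adjusted p = 0.189), and SREBF2 rose (1.08) while PMVK (-0.96) and LSS (-0.80) fell, with STARD4 at 0.60 (adjusted p = 0.11, list adjusted p = 0.785). The metallothioneins with the lowest p were MT1E (-2.75, adjusted p = 0.052), MT1X (-1.70, adjusted p = 0.058), MT2A (-1.52, adjusted p = 0.16) and MT1G (-1.43, adjusted p = 0.21). In KM12SM the lists of p53 targets (median 0.04, adjusted p = 0.846), endoplasmic reticulum chaperones (-0.04, adjusted p = 0.785), cadherins and desmosome (-0.0033, adjusted p = 0.836), oxidative phosphorylation (-0.01, adjusted p = 0.655), ribosomal proteins (0.45, adjusted p = 0.0501), fibroblast markers (0.14, adjusted p = 0.655) and blood cell markers (0.16, adjusted p = 0.663) were not called by camera or fry. The calls for VIL1, SOX9, ITGA3, TNIP1, LSS, SREBF2, FASN and MMP14 were lost in KM12SM when single arrays of the line were left out.

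In SW620, the sh60 arrays showed higher RARB, a retinoic acid receptor, higher A2M, a protease inhibitor, and higher APOBEC3G, a cytidine deaminase of the antiviral defence. RARB rose at least 3.11-fold (log2 fold change 3.27, SE 0.23, adjusted p = 1.6e-07), from 3.66 ± 0.34 (SD, n = 6) to 6.93 ± 0.53 (SD, n = 4). A2M rose by 3.26 and APOBEC3G by 3.04 on the log2 scale. The other genes that rose most were FAM171B (2.33), the growth factor gene BMP6 (2.09), LHFPL6 (2.06), ENPP5 (2.03), SEMA6A, a semaphorin (1.99), HEY2, a transcriptional repressor of the Notch pathway (1.88), and PLOD2, a collagen lysyl hydroxylase (1.86). The extracellular matrix gene TNC (tenascin C) fell at least 6.30-fold (log2 fold change -2.92, SE 0.51, adjusted p = 0.0025), and the protocadherin gene PCDH19 of chromosome X fell by 2.92. CHGB (-2.45), LRIG1, an inhibitor of receptor tyrosine kinases (-2.23), the export pump gene ABCC2 (-2.15), the Notch target HES1 (-2.11), ASB4 (-2.08), TOX3 (-2.04), B3GNT5 (-1.80) and CADPS2 (-1.76) also fell. In all, 629 probes passed, 345 higher and 284 lower, and 125 and 106 of them changed at least 2-fold. With the probes of chromosome X genes left out, 549 passed. Within set 2 there were 1031 called probes, within set 1, with its single sh60 array, 1255, and with the set as a block 1275, which held all 629. Without sh60 array 4 the count was 1726. It was lower with the line fitted alone (224), with the replicate number as a block (227), without sh60 arrays 1 and 3 (331) and without unmodified array 2 (385).

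Sizes differed between the sets for some of these genes. The rule that picked them, by arrays without overlap, fixes their sign within a set. TNC had a log2 fold change of -6.04 in set 1 and -1.63 in set 2, HEY2 had 0.83 and 2.17, and CADPS2 had -0.47 and -2.33. RARB (2.74 and 3.27), LRIG1 (-1.85 and -2.36) and B3GNT5 (-1.64 and -1.61) were closer between the sets.

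Of the 22 DNA replication genes, 3 fell in SW620 and 19 did not pass (8 lower when adjusted over the list alone), namely GINS2 (-1.41), RFC2 (-0.86) and MCM6 (-0.78), with PCNA at -0.74 (adjusted p = 0.059). The list's median was -0.57 (adjusted p = 4.3e-09, and adjusted p = 0.288 with an estimated correlation), -1.34 within set 1, -0.44 within set 2 and -0.80 with the set as a block. Against the unmodified mean, sh60 arrays 1 to 4 had medians of -0.235, -0.16, -0.25 and -1.62. Of the 16 histone genes 0 passed singly and 10 did when adjusted over the list alone. Their median was -0.68 (adjusted p = 5.9e-08, and adjusted p = 0.416 with an estimated correlation), with H3C10 at -1.14, H3C8 at -0.95, H1-5 at -0.90 and H2BC5 at -0.67. The list median was -1.45 within set 1 and -0.62 within set 2, and the medians of sh60 arrays 1 to 4, each against the unmodified mean, were 0.21, -0.33, -0.78 and -1.80. The mitosis list fell with a median of -0.18 (adjusted p = 0.043, and adjusted p = 0.801 with an estimated correlation), and 1 of its 20 members passed, CDC20 (-0.73), also when adjusted over the list alone. AURKA (-0.44), CDK1 (-0.47) and UBE2C (0.33) did not pass. The mitosis median with the set as a block was -0.325 (adjusted p = 1.8e-05, and adjusted p = 0.509 with an estimated correlation). Without sh60 array 4 it was 0.29 (adjusted p = 0.290). In SW620, fry called neither the DNA replication list (adjusted p = 0.083) nor the mitosis list (adjusted p = 0.664).

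Of 17 NF-kB genes 2 rose, TNFAIP3 (1.37) and CXCL1 (0.98), and 15 did not pass (5 higher when adjusted over the list alone), with IER3 at 0.66 and CXCL10, under the background in both groups, at 0.64. The median was 0.43 (adjusted p = 0.00022, and adjusted p = 0.114 with an estimated correlation), 0.53 within set 1 and 0.18 within set 2. Of 18 ERK output genes 4 rose and 14 did not pass (5 higher when adjusted over the list alone), namely the ERK phosphatase gene DUSP6 (1.14), the immediate early gene EGR1 (0.98), SPRY2 (0.69) and EPHA2 (0.56). Their median was 0.29 (adjusted p = 0.00087, and adjusted p = 0.177 with an estimated correlation). DUSP6 had 2.76 within set 1, with its single sh60 array, and 0.54 within set 2. The antigen presentation list rose with a median of 0.28 (adjusted p = 0.0061, and adjusted p = 0.177 with an estimated correlation), and 1 of 16 genes passed, PSMB8 (0.88), with 3 when adjusted over the list alone. PSMB9 (1.003), ERAP1 (0.54) and HLA-DPA1 (0.45, under the background in both groups) did not pass, and without sh60 array 4 the list's call was lost (adjusted p = 0.097).

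The cholesterol synthesis list fell in SW620 with a median of -0.31 (adjusted p = 0.00087, and adjusted p = 0.288 with an estimated correlation), though fry did not call it (adjusted p = 0.075). Of its 19 genes EBP (-0.73), NSDHL (-0.92) and IDI1 (-0.73) fell and 16 did not pass (5 lower when adjusted over the list alone), with CYP51A1 at -0.60. EBP and NSDHL lie on chromosome X, whose genes were lower in sh60 arrays 1 to 3, and the list's median was 0.07 within set 1 and -0.78 within set 2. In the list of oxidative stress and detoxification genes, ABCC2 and AKR1C3 (-1.75) fell and AKR1B10 (0.56, under the background in both groups) rose, 13 of 16 did not pass, and GCLM had -0.68. Adjusted over the list alone the numbers were the same, 2 lower and 1 higher. The median was -0.25 (adjusted p = 0.032, and adjusted p = 0.541 with an estimated correlation), and the call was lost with the set as a block (-0.21, adjusted p = 0.136). Within set 1 the median was 0.037 and within set 2 it was -0.27.

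Several lists held called members in SW620 without a call by camera. Among the 17 intestinal identity genes, VIL1 (-1.73) and the mucin gene MUC13 (-1.45) fell, the keratin gene KRT18 rose (0.55), and ISX had -0.45 (list adjusted p = 0.315). VIL1 had 0.26 within set 1 and -2.75 within set 2. Among the 18 Wnt targets, LGR5 (-1.55), CRIPTO (-1.25) and CD44 (-0.87) fell and APCDD1 had 0.48, with a list median of 0.03, a mean of -0.06 and adjusted p = 0.662. Among the 17 mesenchymal genes TNC, TGFBI (-0.99) and TAGLN (-0.94) fell, LOX, under the background in both groups, had 0.53, and the list's median was 0.04 and its mean -0.21 (adjusted p = 0.341). In the hypoxia and glycolysis list, the mitophagy receptor gene BNIP3L (1.10) and ALDOC (1.002) rose, PGK1 of chromosome X fell (-0.71), and PDK1 had 0.88 (list adjusted p = 0.185). The lists not called by camera in SW620 included p53 targets (median 0.04, adjusted p = 0.993), endoplasmic reticulum chaperones (-0.12, adjusted p = 0.202), integrins and focal adhesion (0.15, adjusted p = 0.756), cadherins and desmosome (0.10, adjusted p = 0.800), type I interferon response (0.18, adjusted p = 0.149, and adjusted p = 0.035 by fry), fibroblast markers (0.14, adjusted p = 0.341) and blood cell markers (0.07, adjusted p = 0.794). With the set as a block the ribosomal protein list was called as well (0.24, adjusted p = 0.0045, and adjusted p = 0.571 with an estimated correlation).

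**Figure D3:**
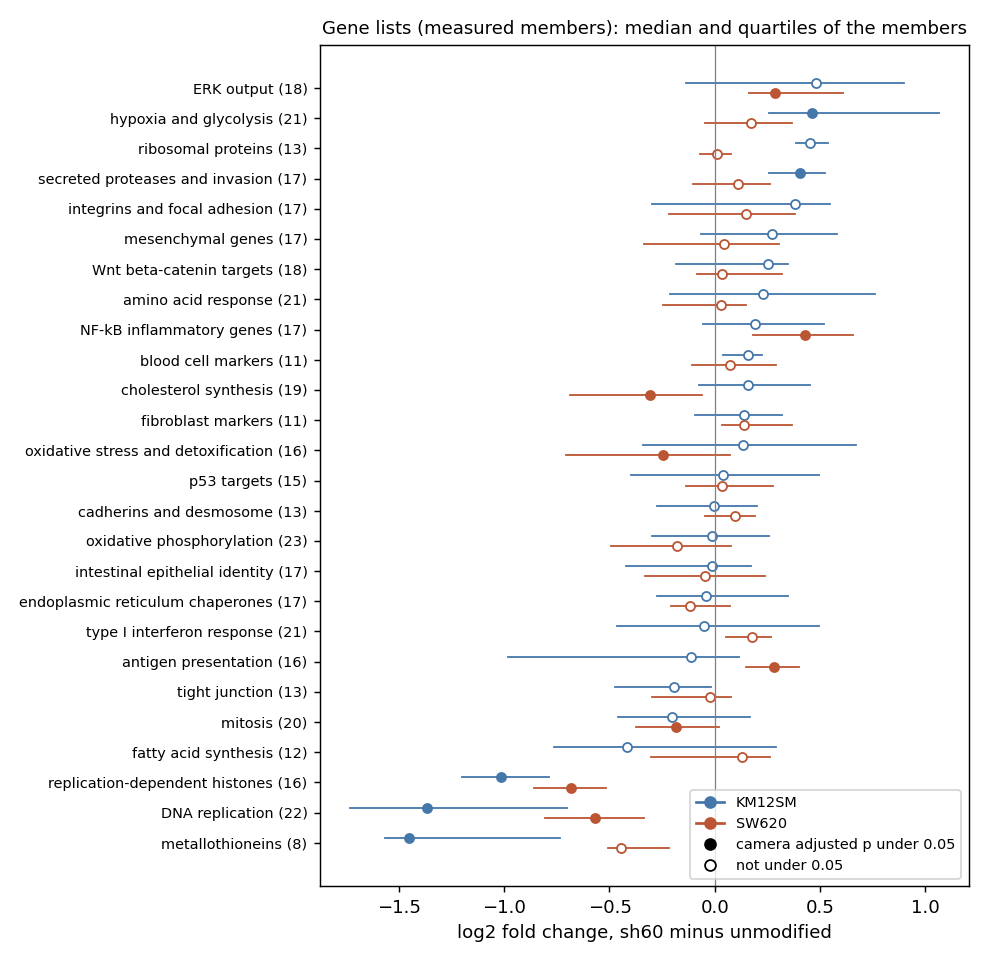
Median (points) and quartiles (lines) of the log2 fold changes, sh60 minus unmodified, of the measured members of each of the 26 gene lists in KM12SM and SW620, with filled points for lists with camera adjusted p under 0.05. The DNA replication medians (-1.37 and -0.57) and histone medians (-1.02 and -0.68) lie below 0 in both lines, and 0 of the calls in either line hold with an estimated correlation.

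Against the SCR control, sh60 arrays of SW620 again held more APOBEC3G (3.12), A2M (2.79), RARB (2.77) and LHFPL6 (2.69), and less ASB4 (-3.08), TNC (-3.02) and CDH17 (-3.00). ESRP1, a splicing regulator of epithelial cells, rose by 3.16, SERPINI1, a serine protease inhibitor gene, fell by 3.29, and AGMO, which cleaves ether lipids, fell by 3.08. SERPINI1 was at 6.415 in sh60, close to the 6.25 of unmodified SW620, and at 9.705 in SCR. ESRP1 was at 10.17 in sh60, 9.335 in unmodified SW620 and 7.01 in SCR. With the set as a block, SERPINI1 (-1.60, adjusted p = 0.077) and AGMO (-1.44, adjusted p = 0.055) did not pass, and ESRP1 had 2.08 (adjusted p = 0.042). Of all probes 552 passed, 293 higher and 259 lower. The comparison has 2 SCR arrays, and without SCR array 1 the count was 73. Against both controls 162 probes changed the same way (95 higher and 67 lower), where independent lists would share 4.71 and 3.43. Both comparisons use the same sh60 arrays, which can add to this. With the sh60 arrays split into pairs, 1 pair per control, 63 to 89 probes were shared, against at most 25.8 for independent lists.

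In gene lists against SCR, ERK output rose with a median of 0.58 (adjusted p = 1.2e-05, and adjusted p = 0.058 with an estimated correlation), and 3 of 18 genes passed (8 when adjusted over the list alone). These were EPHA4 (2.60), FOSL1 (2.10) and IER3 (1.10), named after their values were seen. EPHA4 and FOSL1 were also lower in SCR than in unmodified SW620, so most of their rise against SCR lies in SCR. The NF-kB list rose with a median of 0.56 (adjusted p = 0.00017, and adjusted p = 0.058 with an estimated correlation), with IER3 and CXCL1 (1.26) higher among 17 genes (3 when adjusted over the list alone). The intestinal identity list fell with a median of -0.31 (adjusted p = 0.0050, and adjusted p = 0.118 with an estimated correlation), and 3 of 17 members fell, VIL1 (-2.33), MUC13 (-2.20) and TFF3 (-1.43), with 4 when adjusted over the list alone. Against unmodified SW620, TFF3 had -0.06 in sh60, so its fall against SCR lies in SCR. The list was likewise not called in sh60 against unmodified SW620 (median -0.05, adjusted p = 0.315) and was higher in SCR. DNA replication (median -0.25, adjusted p = 0.0035, and adjusted p = 0.641 with an estimated correlation) and histones (-0.62, adjusted p = 0.00092, and adjusted p = 0.641 with an estimated correlation) fell, with 1 of 22 genes, PCNA (-1.65), and 0 of 16 genes passing singly, and 4 and 0 when adjusted over the list alone. With the set as a block their medians were -0.89 and -1.21. These values rest largely on sh60 array 4. Against the unmodified mean, DNA replication had medians of -0.25 to -0.16 in sh60 arrays 1 to 3, level with SCR (-0.29 and -0.23), and of -1.62 in array 4, while histones had 0.0008 and -0.18 in SCR and 0.21 to -0.78 in sh60 arrays 1 to 3. The oxidative phosphorylation list was called lower with a median of -0.83 (adjusted p = 7.2e-09, and adjusted p = 0.292 with an estimated correlation) and 2 of 23 members lower, 6 when adjusted over the list alone. The ribosomal protein list was called lower with a median of -0.685 (adjusted p = 2.2e-05, and adjusted p = 0.618 with an estimated correlation) and 0 of 13 members passing, 4 when adjusted over the list alone. The fatty acid synthesis list was called higher with a median of 0.595 (adjusted p = 0.046, and adjusted p = 0.618 with an estimated correlation) and 0 of 12 members passing, 4 when adjusted over the list alone. These last 3 calls were lost with the set as a block, at medians of -0.24 (adjusted p = 0.062), 0.10 (adjusted p = 0.993) and 0.05 (adjusted p = 0.652). The block also added calls, whose adjusted p-values can be too small since the sets come from the same values. These were metallothioneins (1.20, adjusted p = 1.8e-06, and adjusted p = 0.232 with an estimated correlation), mitosis (-0.50, adjusted p = 4.3e-06, and adjusted p = 0.320 with an estimated correlation) and amino acid response (0.55, adjusted p = 1.9e-05, and adjusted p = 0.232 with an estimated correlation). Only sh60 array 4 is in the set of the SCR arrays, and against SCR it had medians of 0.09, -0.94 and 0.775 for these lists. The metallothionein call thus does not come from array 4. In sh60 against unmodified SW620 the metallothionein median was -1.15 within set 1 and 0.83 within set 2. A block that assumes the same effect in both sets does not describe that list. Wnt targets (-0.43, adjusted p = 0.012, and adjusted p = 0.200 with an estimated correlation), hypoxia (-0.17, adjusted p = 0.014, and adjusted p = 0.267 with an estimated correlation) and antigen presentation (0.17, adjusted p = 0.043, and adjusted p = 0.320 with an estimated correlation) were added too.

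The SCR arrays differed from unmodified SW620 at 326 probes, 136 higher and 190 lower. With array medians subtracted, 112 were higher and 221 lower. Besides CDH17, SCR held more SERPINI1 (3.46), the keratin gene KRT23 (3.05), the potassium channel subunit gene KCNMB4 (2.91), TMEM176A (2.65) and the adhesion receptor gene ADGRL2 (2.40). It held less of the neurotrophin receptor gene NTRK2 (-2.62), the imprinted gene PEG10 (-2.56), the RNA-binding protein gene QKI (-2.34), ESRP1 (-2.33) and the receptor phosphatase gene PTPRM (-2.18), though ESRP1 did not pass with the set as a block (-1.61, adjusted p = 0.087). Ribosomal protein genes (median 0.65, adjusted p = 2.0e-06, and adjusted p = 0.553 with an estimated correlation) and oxidative phosphorylation genes (0.64, adjusted p = 1.5e-07, and adjusted p = 0.532 with an estimated correlation) were higher as lists, with 1 of 13 and 0 of 23 members passing and 3 and 4 when adjusted over the list alone. Both SCR arrays belong to set 1, and with the set as a block those medians were 0.15 (adjusted p = 0.0153) and 0.32 (adjusted p = 0.0095). With an estimated correlation these blocked calls had adjusted p = 0.562 and 0.275. The intestinal identity list rose (0.22, adjusted p = 0.028, and adjusted p = 0.403 with an estimated correlation), with TFF3 (1.37) the 1 gene of 17 that passed, and so did the interferon list (0.11, adjusted p = 0.010, and adjusted p = 0.333 with an estimated correlation), with IFIT1 (1.79) and OAS1 (1.21) of 21. The fatty acid synthesis list (-0.49, adjusted p = 0.0045, and adjusted p = 0.538 with an estimated correlation), the amino acid response list (-0.36, adjusted p = 0.010, and adjusted p = 0.566 with an estimated correlation) and the ERK output list (-0.27, adjusted p = 0.031, and adjusted p = 0.538 with an estimated correlation) fell, and of ERK output EPHA4 (-1.98) and FOSL1 (-1.77) fell singly. With the set as a block the fatty acid median was -0.41 (adjusted p = 0.043, and adjusted p = 0.538 with an estimated correlation). The block added calls of metallothioneins (-0.995, adjusted p = 8.4e-07, and adjusted p = 0.219 with an estimated correlation), oxidative stress (-0.44, adjusted p = 0.00017, and adjusted p = 0.0922 with an estimated correlation) and hypoxia genes (0.30, adjusted p = 0.00017, and adjusted p = 0.1502 with an estimated correlation). Histones (0.36, adjusted p = 0.0091, and adjusted p = 0.584 with an estimated correlation), tight junction genes (-0.26, adjusted p = 0.022, and adjusted p = 0.1502 with an estimated correlation) and NF-kB genes (-0.23, adjusted p = 0.034, and adjusted p = 0.275 with an estimated correlation) were added as well. TFF3, IFIT1, OAS1, EPHA4 and FOSL1 are named here after their values were seen. Between sh60 and SCR, each against unmodified SW620, 17 probes were higher and 23 lower in both, where independent lists would share 2.19 and 2.52, and the unmodified arrays shared by both comparisons can add to this. Without SCR array 1 the count of 326 was 23, and without sh60 array 4 it was 751.

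The changes common to both lines included lower LGR5, a receptor of intestinal stem cells, and lower SLC12A2, an ion cotransporter gene. LGR5 fell by 2.62 (SE 0.45, adjusted p = 0.00049) in KM12SM and by 1.55 (SE 0.36, adjusted p = 0.0205) in SW620. SLC12A2 fell by 1.55 and 1.41, the replication gene GINS2 by 1.49 and 1.41, the export pump gene ABCC2 by 1.37 and 2.15, the lipid droplet gene PLIN2 by 1.24 and 1.23, and AGMAT by 2.61 and 1.14. VIL1 (-1.47 and -1.73), TRNP1 (-1.41 and -1.17), SRPRB (-1.23 and -1.15) and HMGB3 of chromosome X (-1.12 and -1.23) also fell in both. In SW620, VIL1 had 0.26 in set 1 and -2.75 in set 2. Its KM12SM call was lost when single arrays were left out. SEMA6A rose by 2.21 and 1.99, the NF-kB feedback gene TNFAIP3 by 2.61 and 1.37, CRABP2, which binds retinoic acid, by 2.26 and 1.18, the clock gene PER3 by 1.58 and 1.16, and HEY2 by 1.52 and 1.88. VEPH1 (1.67 and 1.53), PAQR5 (1.59 and 1.34), TET2, a DNA demethylation enzyme (1.42 and 1.48), MCTP1 (1.34 and 1.62) and the kinase gene MAP3K8 (1.30 and 1.22) rose in both. In all, 61 probes rose and 84 fell in both lines, where independent lists would share 20.3 and 21.6 (Fisher's exact test over probes, which are not independent, p = 1.0e-14 and 2.0e-28), and 14 and 20 probes changed in opposite directions, against 16.8 and 26.3. The lines share no arrays. With the set as a block the count of 145 was 410, and without sh60 array 4 it was 321. It was 52 with the replicate number as a block, 69 with each line fitted alone and 79 without KM12SM sh60 array 3. With the probes of chromosome X genes left out it was 128.

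**Figure D4:**
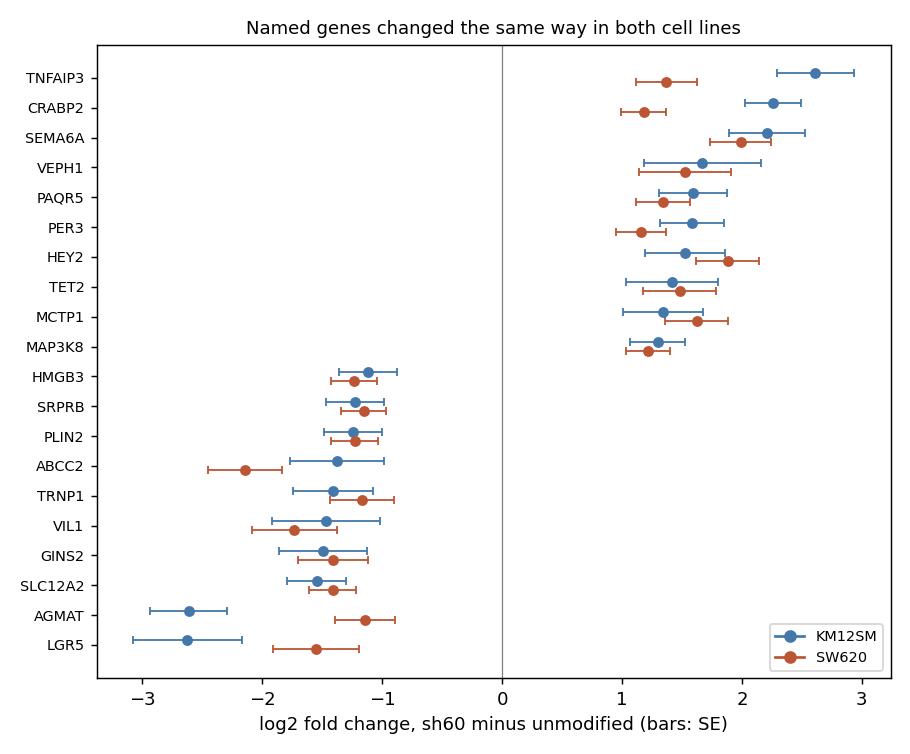
Log2 fold changes (points) and SE (bars), sh60 minus unmodified, in KM12SM and SW620 for the 10 named genes that rose and the 10 that fell in both lines. LGR5 and AGMAT fell by 2.62 and 2.61 in KM12SM and by 1.55 and 1.14 in SW620, and SEMA6A rose by 2.21 and 1.99.

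The response to sh60 differed between the lines for 1230 probes, 532 with the larger value in KM12SM and 698 with the larger value in SW620. With array medians subtracted the split was 424 and 811. Leaving out single arrays gave between 724 and 1709, and 66 of 1000 random splits of the arrays reached 1230, so chance is not excluded for this count. The largest differences, KM12SM effect minus SW620 effect, were for CAPN6 (4.51, SE 0.34), ZBTB10 (3.91), CREB5 (3.83), SESN3 (3.22) and AGMO (3.13), and in the other direction SLC38A5 (-4.68, SE 0.31), CTSE (-4.15), TCEA3 (-3.59), PUDP (-3.39) and CMBL (-3.17). CTSE, TCEA3 and PUDP had signals between 4.09 and 5.20 in unmodified SW620 arrays, against 7.11 to 10.8 in KM12SM. CDH17 itself differed by -3.04 (SE 0.32, adjusted p = 1.1e-05). Its signal in unmodified SW620 was at the background, so it could not fall as far there. DNA replication genes were lower by more in KM12SM (median difference -0.77, adjusted p = 0.0016, and adjusted p = 0.812 with an estimated correlation), with MCM6, MCM3 and UHRF1 passing among 22 genes and 5 when adjusted over the list alone. Antigen presentation genes also differed (-0.40, adjusted p = 0.0067, and adjusted p = 0.272 with an estimated correlation), with ERAP1 (-1.47), PSMB8 (-2.01), PSMB9 (-2.27) and TAP2 (-1.92) among 16 passing, with negative log2 fold changes in KM12SM and positive ones in SW620. Hypoxia and glycolysis genes (0.30, adjusted p = 0.012, and adjusted p = 0.812 with an estimated correlation) and cholesterol synthesis genes (0.50, adjusted p = 0.040, and adjusted p = 0.781 with an estimated correlation) had larger values in KM12SM, with 6 of 21 and 0 of 19 passing, 7 and 0 when adjusted over the list alone. AGMO lost its call when SW620 sh60 arrays 1 and 3 were left out.

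Without silencing, KM12SM carried far more of several secretory and epithelial genes than SW620, and less of the Wnt targets. MAL2, a protein of epithelial membrane traffic, was at least 71.4-fold higher (log2 difference 7.91, SE 0.30, adjusted p = 6.7e-14), at 11.5 ± 0.46 (SD, n = 3) against 3.54 ± 0.42 (SD, n = 6). AGR2, a disulfide isomerase of mucus-secreting cells, was higher by 7.44, REG4 by 7.06, the lysozyme gene LYZ by 7.003, the transporter gene SLCO1B3 by 6.33 and CDH17 by 4.79 (at least 21.4-fold). PHYHIPL (-6.18), the Wnt feedback gene NKD1 (-6.06), FAM111B (-5.92), the leukocyte plastin gene LCP1 (-5.62) and MSANTD4 (-5.50) were lower in KM12SM. Of the 18 Wnt targets 13 were lower and 1 higher (median -1.15, adjusted p = 2.8e-07, and adjusted p = 0.0086 with an estimated correlation), including AXIN2 (-4.92) and NOTUM (-3.67), with CD44 (3.15) higher. Of the 17 intestinal identity genes 9 were higher and 0 lower (median 0.50, adjusted p = 6.7e-07, and adjusted p = 0.0084 with an estimated correlation), including TSPAN8 (4.74) and CEACAM5 (4.16). Of the 13 tight junction genes 5 were higher and 1 lower (median 0.43, adjusted p = 0.0032, and adjusted p = 0.036 with an estimated correlation), including CLDN7 (3.92) and, lower, CLDN1 (-1.51). AXIN2, NOTUM, CD44, TSPAN8, CEACAM5, CLDN7 and CLDN1 are named here after their values were seen. In total 4581 probes passed, 2358 higher and 2223 lower in KM12SM.

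A further 9 lists were called between the unmodified lines at the preset correlation and not with an estimated one. Higher in KM12SM were oxidative phosphorylation (median 1.02, 14 of 23 genes, adjusted p = 6.8e-06, and adjusted p = 0.306 with an estimated correlation), cholesterol synthesis (0.61, 10 of 19, adjusted p = 7.1e-06, and adjusted p = 0.076 with an estimated correlation) and cadherins and desmosome (0.70, 7 higher and 1 lower of 13, adjusted p = 0.00081, and adjusted p = 0.122 with an estimated correlation). Ribosomal proteins (0.63, 3 of 13, adjusted p = 0.0043, and adjusted p = 0.593 with an estimated correlation), the interferon list (0.33, 8 higher and 1 lower of 21, adjusted p = 0.0036, and adjusted p = 0.066 with an estimated correlation) and antigen presentation (0.44, 6 higher and 2 lower of 16, adjusted p = 0.018, and adjusted p = 0.122 with an estimated correlation) were higher too. So were fatty acid synthesis (0.30, 4 of 12, adjusted p = 0.022, and adjusted p = 0.538 with an estimated correlation) and oxidative stress genes (0.61, 6 higher and 3 lower of 16, adjusted p = 0.043, and adjusted p = 0.538 with an estimated correlation). Mesenchymal genes were lower (-0.36, 5 lower and 2 higher of 17, adjusted p = 0.0038, and adjusted p = 0.076 with an estimated correlation). Several of these medians depend on the SW620 array set. Against set 1 and set 2 of unmodified SW620 they were 0.20 and 1.11 for ribosomal proteins, 0.49 and 1.72 for oxidative phosphorylation, 0.88 and -0.16 for fatty acid synthesis, and 0.98 and 0.41 for cadherins and desmosome. In the order Wnt targets, intestinal identity, tight junction and cadherins and desmosome, 15, 12, 6 and 9 members passed in either direction when adjusted over the list alone. The fibroblast (-0.14, adjusted p = 0.204) and blood cell (-0.06, adjusted p = 0.312) marker lists were not called, and of the blood cell list LYZ, which KM12SM also expresses, was the 1 member of 11 that passed.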

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

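Of the tests below, those on compressed signal and X dosage, on level-dependent signal and short genes, and on the share of dividing cells in SW620 with the set as a block were set down before their results were seen. The other tests of the weighed patterns were chosen after. The counts over array splits were set down before too, save the additions named there. Single samples far from the others of their group, and effects that differed between the lines, are given first.

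In 16 of 232 groups of values 1 sample stood apart from the rest, and chance alone gives about 1 in 20. Of these 16 cases, 8 belonged to SW620 sh60 array 4, the only sh60 array of set 1. Its signal was 6.14 for RARB (others 7.13 to 7.25), 11.59 for IER3 (11.14 to 11.19), 6.75 for ASB4 (5.65 to 5.78), 8.43 for IDI1 (7.39 to 7.51), 11.4 for DUSP6 (9.31 to 9.4) and 9.24 for AURKA (10.08 to 10.16). Its DNA replication list had a median of -1.62 (others -0.25 to -0.16) and its ribosomal protein list one of 0.85 (others -0.36 to -0.23). In sh60 array 1, LOX was 5.36, PUDP 5.44 and PCDH19 5.7. Among the unmodified SW620 arrays, SRPRB was 8.75, CXCL1 5.82 and AURKA 9.98 in array 3, AGR2 was 3.34 in array 2 and CXCL10 3.23 in array 4.

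The test of the difference between the lines called 1230 probes, among them 73 of the named genes, given as KM12SM effect minus SW620 effect. Genes that rose in KM12SM alone were CAPN6 (4.51), ZBTB10 (3.91), CREB5 (3.83), SESN3 (3.22), CALB2 (3.10), NEO1 (2.69), MIA (2.68), CREBRF (2.52), ATF3 (2.50) and DDIT3 (2.34). With them rose ODAM (2.245), HMOX1 (1.58), KDM3A (1.47), TFF3 (1.35), ZYX (1.34), CGN (1.25), CEBPB (1.23), PLAUR (1.03), ADM (0.91) and IRF9 (0.89). Genes that fell in KM12SM alone were CTSE (-4.15), TCEA3 (-3.59), PUDP (-3.39), CMBL (-3.17), GASK1B (-2.76), PIGW (-2.51), CCNE2 (-2.36), KCNE3 (-2.28), PSMB9 (-2.27), CLDN2 (-2.22) and UHRF1 (-1.97). So did TAP2 (-1.92), MCM3 (-1.885), LGALS4 (-1.64), OAS1 (-1.53), ERAP1 (-1.47), MYC (-1.425), CLDN7 (-1.26), IFIT3 (-1.25), ELOVL6 (-1.25), CDX1 (-1.18) and ALDH1L2 (-1.04).

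Genes that fell in SW620 alone were PCDH19 (2.95), AKR1C3 (2.65), TOX3 (2.49), CHGB (2.34), HES1 (2.22), ASB4 (1.68), TAGLN (1.52), TGFBI (1.315) and PGK1 (1.04), and those that rose there alone were RARB (-3.155), APOBEC3G (-3.08), A2M (-2.90), BMP6 (-2.01), PLOD2 (-1.91) and FAM171B (-1.58). B3GNT5 (2.74) rose in KM12SM and fell in SW620, and MX1 (-2.80), DUSP6 (-2.71), PSMB8 (-2.01) and CXCL1 (-1.815) fell in KM12SM and rose in SW620. AKR1B10 (-1.48) had the same signs, but it was under the background with and without sh60 in both lines, so its values do not measure expression. Both lines changed the same way, by different amounts, for SLC38A5 (-4.68), CDH17 (-3.04, mostly under the background in SW620), AGMAT (-1.47), ALDOC (1.38), LRIG1 (1.27), LHFPL6 (-1.26), MCM6 (-1.22) and CRABP2 (1.08). AGMO (3.13) and ITGA6 (1.29) passed in neither line alone. The DNA replication (-0.77), antigen presentation (-0.40), cholesterol synthesis (0.50) and hypoxia and glycolysis (0.30) lists differed as well, at adjusted p = 0.812, 0.272, 0.781 and 0.812 with an estimated correlation.

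Chromosome X genes were lower by 0.54 relative to autosomes in SW620 sh60 arrays 1 to 3. With all 4 sh60 arrays against unmodified SW620, camera on each chromosome's expressed genes gave X a median of -0.47. Its adjusted p was 5.6e-29, and 0.082 with an estimated correlation. Most chromosomes were called at the preset correlation. Chromosome 7 was lower (-0.21, adjusted p = 1.5e-09, and adjusted p = 0.082 with an estimated correlation). Chromosome 13 was higher (0.21, adjusted p = 0.00035, and adjusted p = 0.439 with an estimated correlation). The array set gave -0.025 between unmodified arrays, and 0% of 10000 autosomal sets matched on signal level were as low (median -0.63 for X, lowest matched set -0.195), which argues against the set and against compressed signal. Loss of X dosage in part or all of the cells predicts lower values along the whole chromosome, and the highest median among 10 bins of neighbouring X genes was -0.19, as that explanation needs. A response to silencing cannot be told apart from it, since the value of 0.0033 in sh60 array 4 comes from 1 array and the -0.032 of KM12SM sh60 from another line.

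The unmodified SW620 arrays 1 to 3 and 4 to 6 differed in metallothionein, oxidative phosphorylation and ribosomal protein genes. Among 10000 lists matched on level, at most 0.08% had a median as low, which argues against signal level as the sole cause. Among lists matched on level and gene span it was at most 1.76%. That is weak for 3 lists picked as low in these same arrays. Gene span is a length on the genome, so short transcripts were not tested and cannot be excluded. The sets were made from these arrays, so the 1917 probes that differed only restate them. A culture or handling batch could give them, but the labels name no batch, so it cannot be told apart from other causes. No biological explanation was tested.

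The DNA replication list was called lower in sh60 arrays of both lines (adjusted p = 0.527 in KM12SM and 0.288 in SW620 with an estimated correlation), but SW620 sh60 arrays 1 to 3 (-0.25 to -0.16) lay below unmodified arrays 4 to 6 only and level with unmodified arrays 1 to 3 (-0.41 to -0.16). With the array set as a block the SW620 median was -0.80, against -0.57 without it. The blocked value joins -1.34 within set 1, from sh60 array 4 alone, and -0.44 within set 2. It is pulled down by 1 array, and the sets were made from these same arrays, so it cannot decide whether the set is the cause. In SCR against unmodified set 1 arrays the median was -0.0125, whereas sh60 array 4 had -1.34. That comparison holds 1 sh60 array, and sh60 arrays 1 to 3 lay level with SCR (-0.29 and -0.23). Handling shared with SCR can therefore not be told apart in SW620, and KM12SM has no SCR arrays. A smaller share of dividing cells would lower mitosis genes alike, yet the lower quartile of mitosis changes lay above the upper quartile of replication changes by 0.245 in KM12SM and by 0.169 in SW620 sh60 arrays 1 to 3, which argues against it there. In sh60 array 4 the value was -0.348, and with the block it was 0.059, past the bound set beforehand but by less than the spread between the sets and with a lower mitosis list (-0.325), so in array 4 and in SW620 as a whole it cannot be told apart. A response to CDH17 silencing stays a hypothesis, since 1 shRNA was used.

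Other splits of the arrays into groups of the same sizes were counted, the real split included. The count over all 210 splits and the larger draw were added after the results were seen. For silencing in KM12SM, 1 of 10 splits gave 2897 probes and the highest other gave 0, and 10 splits are too few for a share under 0.05. For silencing in SW620, 3 of 100 drawn splits reached the real 629 (highest other 1877), and 5 of all 210 did, which is 2.38%. The highest of all was 3242. That split follows the array sets and points to a structure of the samples. Since the splits do not keep the sets apart, they cannot exclude chance for this count. Within set 2 the count was 1031, and with the block it was 1275. Between the unmodified lines 1 of 84 splits, the real one, reached 4581, which is the smallest share that 84 splits allow. As the labels do not say that replicates are separate cultures, this excludes chance only for the spread between these arrays. The highest other count was 2227, from the KM12SM arrays joined with SW620 arrays 4 to 6. For genes changed in both lines 1 of 100 reached 145 (highest other 26, and 76 in a larger draw of 1000). These draws relabel both lines at once, and other KM12SM splits call 0 probes, which leaves nothing to share. They therefore cannot test the overlap between the lines. For the difference between lines 7 of 100 reached 1230 (highest other 2890), and in the larger draw 66 of 1000 did (highest other 2974), so chance cannot be excluded. For the 13 list calls of the silencing comparisons, 16 of 100 splits gave as many (highest other 16), and 163 of 1000 in the larger draw (highest other 19), so chance cannot be excluded.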

How the results depend on the processing

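The array set as a block, comparisons within a set, the loss of sh60 arrays 1 and 3 and the removal of X probes were chosen after the data were seen. Of 214 results, 203 kept their direction and side of the threshold with quantile normalization, 205 with array medians subtracted, 203 with trend and robust moderation, 194 with array weights and 193 with the set as a block. With dim probes left out 190 of 196 did, with 1 value per gene 213 of 214, against the mean of both controls 54 of 67, and without X probes 159 of 163. Single lost arrays left between 190 and 202 of 214. Each line fitted alone kept 157 of 192, and a log2 fold change of at least 1 kept 165 of 201. Set 2 alone kept 62 of 75, and the loss of sh60 arrays 1 and 3 kept 188 of 214. Of the 13 list calls, fry kept 6 and camera with an estimated correlation 0.

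Each line fitted alone gave 5683 probes for silencing in KM12SM, 224 in SW620, 149 against SCR, 70 for SCR and 69 in both lines. Array weights gave 9263 for KM12SM, 1658 against SCR, 1140 for SCR, 3689 for the line difference, 8962 at baseline and 339 in both lines. With an absolute log2 fold change of at least 1 there were 1494 in KM12SM, 231 in SW620, 2302 at baseline and 35 in both lines, since fewer probes can pass. The same sign against both SW620 controls left 162. Leaving out sh60 arrays 1 and 3 gave 331 for SW620, 347 against SCR and 661 for SCR. The set as a block gave 1275 for SW620, 1976 for the line difference and 410 in both lines. Set 1 alone gave 1255 for SW620, 879 against SCR, 1068 for SCR and 430 in both lines, and set 2 alone 1031 and 298. In set 1 the cholesterol list (0.067) and VIL1 (0.26) in SW620 turned direction, and so did the oxidative stress median (0.037). The cause was not tested for any of these unless stated.

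With 1 array left out at a time, counts ranged from 1823 to 3359 for KM12SM, 385 to 1726 for SW620, 73 to 2439 against SCR, 23 to 751 for SCR, 724 to 1709 for the line difference, 3390 to 5108 at baseline and 79 to 321 in both lines, with the highest all without SW620 sh60 array 4. List calls ranged from 10 to 16. The SW620 mitosis median ranged from -0.32 to 0.29, turning direction without sh60 array 4. Where SCR keeps 1 array, its spread is taken from the other groups.

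Arrays of different groups share only a replicate number. The deviations of unmodified and sh60 arrays correlated with r of 0.49, 0.29 and -0.05 in KM12SM and of -0.10 to -0.43 in SW620, those of SCR and sh60 arrays with 0.35 and 0.17, and those of unmodified and SCR arrays with -0.12 and 0.35. Most arrays correlated best with another number. The replicate number as a block gave 227 for SW620, 161 against SCR, 58 for SCR, 794 for the line difference, 1634 at baseline and 52 in both lines, and it left 174 of 214 results unchanged in direction and call.

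Weak genes are limited by the background. CDH17 in SW620 sh60 arrays stood between the 8.40th and 17.9th percentile of all probes, where array signal is compressed towards the background.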

Other observations

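The 3 gene lists here were drawn up after the results were seen, from genes in the tables of silencing. A test of such a list restates what led to it, so only members and medians are given. In KM12SM, of 16 genes of the circadian clock 8 rose and 1 fell, with the repressor genes CRY1 (2.75), NR1D1 (1.86), PER2 (1.78) and PER3 (1.58) and the clock output gene BHLHE40 (1.77) higher and CLOCK (-1.14) lower. The median of these genes was 0.78 in KM12SM, 0.10 in SW620 against unmodified arrays and 0.28 against SCR.

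Of 18 genes of ribosome biogenesis, which make and process ribosomal RNA, 13 fell in KM12SM, including WDR3 (-2.21), GRWD1 (-2.21), the RNA polymerase I subunit POLR1A (-1.75) and NIP7 (-1.49). Their median was -0.89. In SW620 the median was -0.33 with 0 of 18 passing, against SCR it was 0.165, and in SCR against unmodified SW620 it was -0.38 with 2 lower. Of the 7 APOBEC3 genes, which encode antiviral cytidine deaminases, APOBEC3G (3.04), APOBEC3F (1.73) and APOBEC3D (1.16) rose in SW620, with a median of 0.86 for the family. Against SCR 4 of the 7 rose, and in KM12SM 0 did (median 0.14).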
